A study of Cucumis x hytivus and Cucumis hystrix and Cucumis sativus with 8 samples.

How the data were processed

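Small RNA was profiled in leaves of a synthetic Cucumis allotetraploid and its diploid parents, in 8 libraries that the sample titles put into 4 groups of 2: allotetraploid young leaf, allotetraploid mature leaf, C. hystrix mature leaf and C. sativus mature leaf. Replicate numbers came from the same titles. Nothing in the labels states that the replicates of a group are separate plants, so the p-values measure only the spread between these samples, which may be technical. Total RNA was taken up in TRIzol and sequenced on an Illumina HiSeq instrument, per the labels' protocols. Those protocols also mention oligo(dT) beads, which select polyadenylated RNA, without a separate description of a small RNA library.

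The values came from 1 table of listed miRNAs. Bowtie 0.12.8 is named in the submitters' processing notes. The genome build, the miRBase release, the mismatches allowed and the counting rule are not given in the sources used here, and coordinates are printed as the table lists them. Nor is the species of the genome given. Of 728 lines with a position, 711 lie on chromosomes 1 to 7, and tested names with a family number begin with csa. If the genome was that of 1 parent, sequences that only the other parent carries could be missed or undercounted. Comparisons between species and with the mid-parent thus cover the listed sequences only. The deposited raw reads, so named per the file headers, were treated as estimated counts: 80.5% of them are whole numbers within 1e-6, and the others hold fractions. The deposited normalized reads were treated as a signal: in each library they equal the raw reads times 1 constant, and how the authors chose that constant is not given in the sources used here. Since the files turned out to hold estimated counts, the count test fixed for that case was used, after rounding to whole numbers.

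The table has 843 lines with values, for 733 different mature sequences of 18 to 25 nt. A sequence listed at more than 1 locus (101 sequences, 0 of them with different values between loci) was taken once, with the value of 1 locus. Whether such a value is a share of the reads of the sequence or all of them is not given in the sources used here, so levels of sequences with different numbers of loci are not on one scale, while ratios of 1 sequence between libraries are unaffected. Of the 733 entries, 446 carry a family number (128 families) and 287 have a name that begins with PC and carries none. The table marks 55 entries as a sequence already in miRBase, 234 as a different sequence of a miRNA listed there and 444 as new, per the file headers. No gene annotation was used here, so whether a locus lies in a gene is not stated. The columns of per-sample values that matched no sample numbered 0.

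Tests were made with edgeR 4.0.16 in R 4.3.3. Entries were kept by filterByExpr over the 4 groups (208 of 733; at least 99.47% of the reads of each library), libraries were scaled by TMM, and the quasi-likelihood test was fitted with robust estimation over all 8 libraries with group as the only term, which leaves 4 residual degrees of freedom. P-values were two-sided and Benjamini-Hochberg adjusted over the 208 entries within a comparison, with a threshold of 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the F statistic. Values in CPM are counts relative to the TMM-scaled library size. The comparisons were young against mature leaf of the allotetraploid, the mature allotetraploid against each parent, C. hystrix against C. sativus, and the mature allotetraploid against the mid-parent, the mean of both parents on the log scale. For family sums the reads of every line of a family were added, loci included, so their CPM have a larger total than those of single entries. They were scaled, tested and adjusted in the same way, together with the single entries that have no family number.

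The miRNA lists, the tests, the rule for named entries and most alternatives were fixed before the data were examined. The lists were made from family numbers: juvenile/adult phase (miR156, miR157, miR172), auxin signalling (miR160, miR167, miR390, miR393, miR847), copper protein (miR397, miR398, miR408, miR857), nutrient (miR395, miR399, miR827, miR826, miR2111, miR169), leaf growth (miR159, miR319, miR396, miR164, miR165, miR166, miR171, miR170), resistance gene (miR482, miR472, miR2118, miR1507, miR5300), small RNA machinery (miR162, miR168, miR403), GRAS/SCL (miR171, miR170), phloem sap, shoot apex or primordia (both as markers of other parts that a leaf sample can hold), and conserved families. Each list was tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over 50 list tests, with camera with an estimated correlation and with fry beside it. The p-value of fry tests whether the members of a list move, on balance, one way, and its mixed p-value whether they change in either direction. Neither compares a list with other lists.

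Entries were named by a fixed rule. In each comparison it took up to 10 called entries per direction with the largest fold change, whose library values do not overlap between the groups and whose mean reaches 10 CPM in a compared group, and the most abundant entry of each list family if called. It also took the 10 most abundant entries for the description of the data. Where fewer than 5 entries passed, the 5 with the largest fold changes in each direction were taken as values without a call. Entries named outside this rule, family sums picked as examples and the fragment-like families were chosen after their values were seen. The fragment-like group holds 12 families whose sequences are known from, or resemble, ribosomal or transfer RNA or whose standing as miRNAs has been questioned; no genome was used here to check them.

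Alternatives were DESeq2 1.42.0, DESeq2 size factors (RLE), library totals and the summed conserved families as scalings, no filter, a filter of a mean of 10 CPM in every compared group, only the groups compared, the replicate number as a block, each library left out in turn, sums by family, every line kept, a minimum fold of 2, limma on log2 of the deposited normalized reads with pseudocounts of 0.5, 1 and 5 (entries at 10 or more in at least 2 libraries), the same without that filter or with quantile normalization, and a mid-parent on the linear scale. Chosen after seeing the data were reads summed over loci, the fragment-like families left out, and the pseudocount of 1. The scalings moved the median log2 ratio of all entries by −0.20 between young and mature leaves (conserved families), by 0.21 and 0.25 against C. hystrix (totals, conserved families), and by −0.26, −0.70 and −1.17 against C. sativus (RLE, totals, conserved families). The shifts were −0.24, −0.87 and −1.42 between the parents and −0.16, −0.24 and −0.50 against the mid-parent.

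A floor of 3 counts limits what a library can show, between 7.6 and 17.7 CPM. A fold against a group with no reads is given as a lower bound against 3 counts over that group, and a ratio with 1 to 3 counts is given with its 95% exact counting interval. Against the mid-parent, such entries are given by their levels alone. Floors and intervals cover counting error only, since reads made by PCR are not independent molecules. Replicates differed by more than sampling noise in every group (chi-square per degree of freedom 38.7 in young leaves, 180 in mature allotetraploid, 107 in C. hystrix and 508 in C. sativus), so no pair was treated as a single library deposited again. Repeat libraries of one RNA would differ by more than sampling noise too, so this does not tell technical repeats from separate plants.

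The scripts were tested on simulated data drawn for the 208 entries, with 40 changed entries in each of 10 sets. Of simulated 16-fold changes, 32% were called between young and mature leaf, 33% between the allotetraploid and C. hystrix, 43% between the allotetraploid and C. sativus, 33% between the parents and 60% against the mid-parent. Of 4-fold changes the shares were 6%, 5%, 3%, 5% and 11% in the same order. With no change simulated, 5% of 100 list tests by camera with the preset correlation had an unadjusted p under 0.05. Entries were drawn independently there, whereas the copper-protein entries had an estimated correlation of 0.79 in the test of young against mature leaves. The 5% thus does not give the error rate for lists whose members move together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.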

Results

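Leaf small RNAs were compared between a synthetic allotetraploid, Cucumis × hytivus, in its 10th selfed generation, and its diploid parents, the wild C. hystrix and the cucumber C. sativus. Mature leaves, the first to be fully grown, stood for all 3 species, and young leaves, the first from the top, for the allotetraploid alone. Each of the 4 groups had 2 libraries, and nothing states that these were separate plants, so the p-values below measure only the spread between these samples, which may be technical. The libraries held between 177757 and 1186178 listed reads and detected between 335 and 562 of 733 entries. The Spearman correlation between the libraries of a group was 0.952 for young leaves, 0.841 for mature allotetraploid leaves, 0.823 for C. hystrix and 0.572 for C. sativus, over the 208 entries tested. The last pair, the least alike, enters both comparisons with C. sativus and the mid-parent.

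A pair of conserved families filled most libraries. miR166, which limits HD-ZIP III transcription factors in the building of leaf faces and meristems, took 83% and 76.1% of listed reads in young leaves, 71.4% and 70.9% in the mature allotetraploid, 81.5% and 78.8% in C. hystrix, and 46.4% and 42.8% in C. sativus. With the fragment-like families described below set aside, its share was 55.5% and 81.6% in C. sativus against 77.5% to 87.2% in the other libraries, so the low share in the second C. sativus library went with its fragment reads. miR159, a regulator of GAMYB-like MYB factors, took 6.98% to 16.8% in the allotetraploid and C. hystrix, and 27.5% and 4.09% in C. sativus. The most abundant single entries were miR166a (TCGGACCAGGCTTCATTCCCC, listed at 4 loci) at a mean of 424562 CPM over all libraries and miR159a (TTTGGATTGAAGGGAGCTCT) at 292619 CPM. After them came miR5368-p5 (58282 CPM), miR166g (40080), miR2916-p3 (37042), a miR166a variant that begins with G (GCGGACCAGGCTTCATTCCCC, 19036), miR894 (16835), miR408 (11669), miR398a (11419) and miR5368-p3 (10576). The sequences of miR5368 and miR2916 are known from plastid and nuclear ribosomal RNA, and miR894 is a questioned miRNA. Together with 9 similar families they made up 3.27% and 4.04% of reads in young leaves, 10.7% and 8.48% in the mature allotetraploid, 6.61% and 8.04% in C. hystrix, and 16.4% and 47.6% in C. sativus. All these shares count every listed locus, so sequences at several loci weigh more. With each sequence counted once, miR159 held 18.3% to 37.6% in the allotetraploid and C. hystrix and 46.6% and 6.47% in C. sativus. miR166 then held 44.1% to 60.6% and 22.2% and 26.3%, and the fragment-like families 6.17% to 17.3% and 17.4% and 58%, in the same order.

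**Figure D1:**
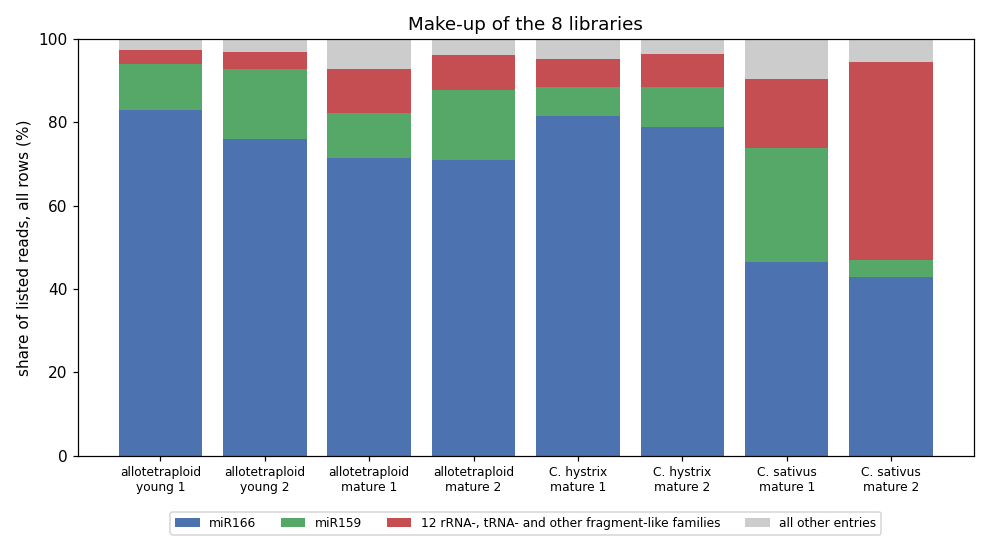
Stacked bars, 1 per library, give the share of listed reads (%, y axis, every locus counted) held by miR166, miR159, 12 fragment-like families and all other entries. The second C. sativus library carries 47.6% fragment-like reads, against 3.27% to 16.4% in the other libraries.

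Leaf age within the allotetraploid, which goes with position on the plant, was addressed by young against mature leaves, and 3 of the 4 entries called were copper-responsive miRNAs. miR397, which acts on laccase transcripts, and both arms of miR408, whose targets include plantacyanin, were far lower in young leaves. These miRNAs are made when copper is short and spare the metal for plastocyanin by removing messages of other copper proteins. miR408 (ATGCACTGCCTCTTCCCTGGC) fell from 10809 ± 9265 CPM (mean ± SD of 2 libraries) in mature leaves to 175 ± 140 in young leaves (log2 fold change −5.95, SE 1.39). Its opposite arm miR408-5p (CGGGGAACAGACAGAGCATGA), listed in the same interval of chromosome 5 (20905079–20905292, plus strand), fell from 2305 ± 2315 to 13.2 ± 6.36 CPM (−7.39, SE 1.56). miR397 (TCATTGAGTGCAGCGTTGATG; chromosome 1, 7211715–7211804, plus strand) fell from 4992 ± 5918 to 38.5 ± 17.3 CPM (−7.00, SE 1.62). The fourth was miR156i-p3 (TAGTATGTGCTCATTTCTCTTT; chromosome 2, 1701649–1701821, plus strand), from the precursor arm opposite a miR156, the family that holds SPL factors down in the juvenile phase. It was at 35.83 and 271.3 CPM in the mature libraries and at least 41.4-fold lower in young leaves, which had no whole read of it, a bound that pools both mature libraries. All 4 had an adjusted p of 0.029 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 0 entries rose, though 7 of the 27 entries at unadjusted p < 0.05 were higher in young leaves. With RLE scaling 1 entry was higher and 6 were lower. DESeq2 called 17 entries, 5 of them higher, and limma called 4. Scaling to the conserved families left 0 calls in edgeR (23 at unadjusted p < 0.05), as did leaving out either young library (13 each). miR397 was also lost without the first mature library (adjusted p = 0.11, in a range of 1.3e-07 to 0.33 over its alternatives). miR156i-p3 was lost without the second (0.25, range 1.7e-04 to 0.44) and passed in 13 of 23 alternatives.

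The copper miRNAs differed widely between the mature libraries, yet the young ones lay lower still. Summed by family, miR397 was at 3967 and 384.6 CPM in the mature libraries and at 19.7 and 10.71 in the young ones (−7.14, SE 1.24, adjusted p = 1.8e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over families and entries without a family). The miR408 family fell by 6.24 log2 units (SE 1.28, adjusted p = 7.3e-05). The miR398 family, which acts on Cu/Zn superoxide dismutase messages, fell from 8332 ± 8640 to 494 ± 117 CPM (−4.08, SE 1.15, adjusted p = 0.015). All of these family falls kept their sign and passed under each of the scalings. Its main entry, miR398a (TGTGTTCTCAGGTCGCCCCTG), at 694 ± 215 against 18316 ± 19695 CPM, was not past the threshold alone (−4.72, SE 1.27, adjusted p = 0.072). miR398b, at +0.21, did not follow.

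**Figure D2:**
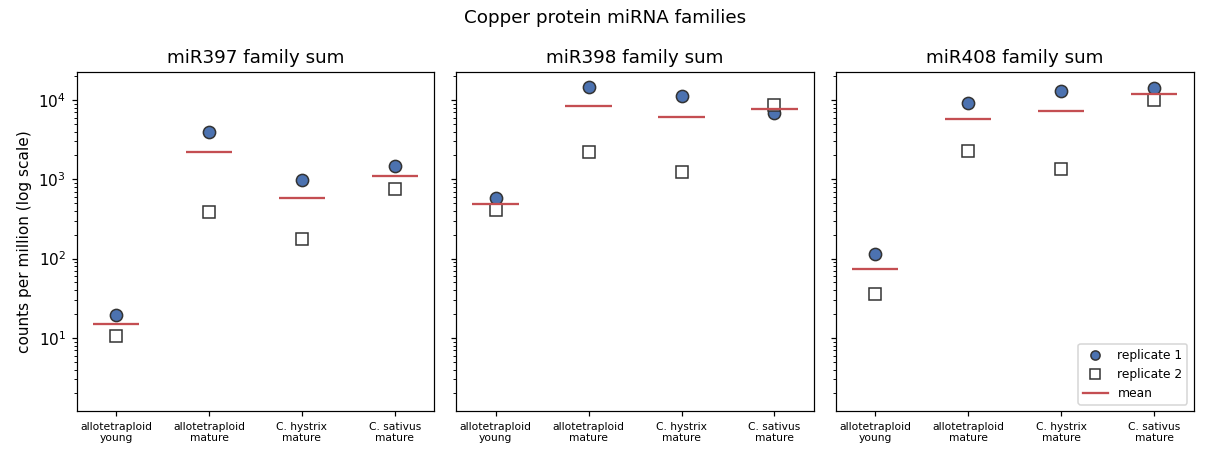
Summed reads of the miR397, miR398 and miR408 families (CPM, log y axis) are drawn for each library in the 4 groups, with a filled circle for replicate 1, an open square for replicate 2 and a red line for the group mean. Both young libraries lie below every mature library for all 3 families, and replicate 1 lies above replicate 2 in C. hystrix and in the mature allotetraploid.

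Regulators of the juvenile phase and of growth had large values without a call. Mature miR156, which declines with the age of the plant in many species, was lower in young leaves: miR156b (TTGACAGAAGATAGAGAGCAC) was at 641 ± 13.4 CPM in young and 9954 ± 175 in mature leaves (−3.96, SE 1.17, adjusted p = 0.11), and miR156f at 8.36 ± 4.66 and 411 ± 137 (−5.56, adjusted p = 0.088). Young leaves were the first from the top, so leaf age and position on the plant differed together. Their effects cannot be told apart here. The miR156 family sum was at 2355 and 2615 CPM in young against 11576 and 12422 in mature leaves (−2.27, SE 1.06, adjusted p = 0.33). miR172b, of the family that acts on AP2-like factors and usually opposes miR156, was at 174.9 and 166.2 CPM in young and 277.7 and 368.7 in mature leaves (−0.92, adjusted p = 0.8). Higher in young leaves were miR171e-p5 (TATTGGTCCGGTTCACTCAGA, 1615 ± 94.4 against 120 ± 115 CPM, +3.75, SE 1.15, adjusted p = 0.12) and miR171d-p5 (259 ± 21.7 against 8.96 ± 12.7 CPM, +4.86, adjusted p = 0.22). Both are entries of the 5p arm, but such entries did not move together. In young against mature leaves, miR171g-p5 (382.7 and 279.8 against 89.58 and 3.478 CPM) and miR171j-5p (253.4 and 361.5 against 62.7 and 114.8) were higher. Lower were miR171u-p5 (12.67 and 5.83 against 138.8 and 111.3) and miR171c-p5 (12.67 and 0 against 44.79 and 104.4). Entries without the 5p mark differed less than miR171e-p5 and miR171d-p5. miR171a was at 1133 and 839.5 CPM in young against 219.5 and 247 in mature leaves, and miR171c at 1232 and 927 against 658.4 and 779.2. The sum of the miR171 family, which acts on GRAS factors that limit chlorophyll formation and maintain meristems, differed by +1.26 (SE 1.00, adjusted p = 0.86 in edgeR's quasi-likelihood test). miR390a, the trigger of TAS3 tasiRNAs that limit auxin response factors, was at 632 ± 131 against 57.7 ± 32.4 CPM (+3.45, adjusted p = 0.27). The 5p arms miR166e-5p (+3.18, adjusted p = 0.19) and miR166g-5p (GGAATGTTGGCTGGCTCGAGG, +2.85, adjusted p = 0.26) were higher too. miR397-p3 was at least 9.63-fold lower (adjusted p = 0.16) and miR396c-3p, of a family that limits growth-regulating factors, at least 12.5-fold lower (adjusted p = 0.16). These bounds pool mature libraries at 62.7 and 20.87 CPM for miR397-p3 and at 26.87 and 69.57 for miR396c-3p. PC-20-3p was at least 2.77-fold higher (adjusted p = 0.41), a bound carried mostly by 1 young library (27.88 and 2.915 CPM). PC-58-3p had 28 reads against 1 (counting interval of the ratio 3.21–793, adjusted p = 0.5). Without the second C. sativus library, which is in neither group but enters the shared estimate of spread, 24 entries were called. They included 6 of miR156 lower, and 4 of miR171, 2 of miR390 and 2 miR166 5p arms higher, and also fragment-like entries lower in young leaves, 3 of miR5368 (−2.25 to −2.44), miR6173 (−2.56) and miR4995 (−3.85), so RNA fragments differed along with miRNAs (miR171e-p5 adjusted p = 2.2e-04, the lowest in a range up to 0.66 over its alternatives).

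With the preset correlation of 0.01, camera called the copper-protein and phase lists lower in young leaves. It called the leaf-growth list higher, a call that fewer alternatives shared. The correlations estimated from the data were 0.79, 0.55 and 0.11 for these lists, all above the preset. The copper-protein list had 8 of 10 entries below 0, with a median of −4.65 (−3.62 with 2 entries at their bounds). 3 entries fell with adjustment over all entries and 6 over the list alone (camera adjusted p = 8.7e-05, and adjusted p = 0.95 with an estimated correlation). The juvenile/adult phase list had 15 of 19 below 0 and a median of −1.43. 1 entry fell over all and 5 over the list alone (camera adjusted p = 0.0019, and adjusted p = 0.95 with an estimated correlation). The leaf-growth list had 34 of 49 above 0 and a median of +0.74, with 0 entries called over all or over the list alone (camera adjusted p = 0.028, and adjusted p = 0.95 with an estimated correlation). That call passed in 9 of 18 alternatives (0.0086 to 0.95), and was lost without young 2 (0.071), mature allotetraploid 1 (0.34), C. hystrix 2 (0.11) or C. sativus 2 (0.068). None of the 4 list calls of the study held with an estimated correlation, and fry, which asks if members move on balance in a shared direction, gave adjusted p = 0.81 for each. The remaining lists had no call. Their medians and camera adjusted p were +0.42 and 0.26 for auxin signalling, −0.14 and 0.8 for nutrient, and +0.72 and 0.7 for small RNA machinery. They were +1.33 and 0.089 for GRAS/SCL, −1.67 and 0.26 for phloem sap, and +0.84 and 0.055 for shoot apex or primordia. In the phloem sap list 1 entry was lower over the list alone. The conserved families had a median of +0.24 but a mean of −0.39 (camera adjusted p = 1). Changes in either direction were found there by the mixed test of fry (adjusted p = 0.037), with 4 entries lower over all and 6 over the list alone. The resistance-gene list had 5 entries in the table and 0 that could be tested.

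Change against the C. hystrix parent was answered in mature leaves, where no entry was called. Among abundant miRNAs, miR166a was at 430944 ± 103278 CPM in the allotetraploid and 631428 ± 13128 in C. hystrix (−0.55), miR398a at 18316 and 15278 ± 17555 (+0.26), miR408 at 10809 and 17360 ± 20408 (−0.68), and miR397 at 4992 and 1472 ± 1490 (+1.76). Among entries that met the naming rule, lower values were those of miR171c-p3 (2.5 reads against 15, counting interval of the ratio 2.13–81.1), the predicted PC-169-5p (3757 ± 153 against 17332 ± 9124 CPM, −2.21, SE 1.12), miR156e (−1.80), PC-132-5p (−1.74) and miR390d-p3 (74.1 ± 47.7 against 242 ± 58.7 CPM, −1.70). Higher values were those of miR156d-p3 (35 reads against 1, counting interval 5.2–1258), PC-124-3p (+2.01), miR172c-p5 (215 ± 139 against 59.6 ± 51 CPM, +1.82), an entry of miR156b (+1.43) and miR171u-p5 (+1.12). The reads of miR156d-p3 came mostly from 1 allotetraploid library (8.958 and 114.8 CPM). The edgeR quasi-likelihood test called 0 of 208 entries, with 0 at unadjusted p < 0.05 and a smallest adjusted p of 0.98 after Benjamini-Hochberg adjustment. DESeq2 called 0 with 2 at unadjusted p < 0.05, and limma called 0 with 0. Since 33% of simulated 16-fold changes were called here, large differences may still have been missed. No list was called either: the median was −0.41 for auxin signalling (camera adjusted p = 0.055), +0.41 for phloem sap (0.13) and +0.48 for copper protein (0.26), and the other lists had adjusted p from 0.75 to 0.89.

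Against the C. sativus parent the edgeR test called 1 predicted miRNA. PC-169-5p (TCGGGAATAGCCACACAACTC; chromosome 7, 8370983–8371159, minus strand), a sequence without a family number and without a known role, rose to 3757 ± 153 CPM in the mature allotetraploid from 11.8 ± 16.7 in C. sativus (+8.16, adjusted p = 0.0085 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The size of this ratio is loosely fixed, since the C. sativus libraries had 23.56 and 0 CPM, and it was +13.02 without the first of them. miR171u-p5 was found at 125 ± 19.5 CPM in the allotetraploid, at least 20.3-fold above C. sativus (adjusted p = 0.2). PC-131-3p (261 ± 14.5 against 16.8 ± 23.8 CPM, +3.84, adjusted p = 0.3), miR156i-p3 (+3.52, adjusted p = 0.58) and miR156f (+3.47, adjusted p = 0.58) followed. In the C. sativus libraries PC-131-3p was at 33.66 and 0 CPM and miR156f at 70.68 and 0. Without the first of these libraries their ratios were +9.18 and +9.87, so their sizes are loosely fixed too. On the other side, miR393b-p3, from the family that acts on the TIR1/AFB auxin receptors, was at 47.7 ± 35.8 against 342 ± 197 CPM (−2.82, adjusted p = 0.58). miR408a-3p (−2.67), PC-24-5p (−2.47) and PC-142-5p (−2.39) had adjusted p = 0.84, and PC-20-3p was at least 4.82-fold lower (adjusted p = 0.62). The main miR166a entry was higher in the allotetraploid without a call (+1.88, SE 0.55, adjusted p = 0.22). miR393c, at 23.6 ± 20.7 CPM in the allotetraploid, had 20.2 and 1680 CPM in the C. sativus libraries, so its ratio of −5.11 rests on 1 library (adjusted p = 0.27). The edgeR test called 1 of 208 entries, with 13 at unadjusted p < 0.05, of which 9 were higher in the allotetraploid. Since 43% of simulated 16-fold changes were called here, large differences may have been missed. Besides PC-169-5p, DESeq2 passed miR393c (DESeq2 adjusted p = 0.0036), miR171u-p5 (0.022) and PC-131-3p (0.04). DESeq2 called 4 entries and limma 1, and without the first C. sativus library edgeR called 55. The lists had no call, with camera adjusted p of 0.055 for both juvenile/adult phase (median +0.98) and copper protein (−0.76). Leaf growth (+0.35) and conserved families (+0.39) had 0.26, shoot apex or primordia (+0.56) and small RNA machinery (−0.49) 0.3, and nutrient (+0.91) 0.74. Auxin signalling (−0.05) had 0.8, as did GRAS/SCL (median −0.04, mean +0.46, with 1 entry called over the list alone) and phloem sap, whose median of +0.35 lay opposite to the direction of its test. The directional test of fry passed shoot apex or primordia (unadjusted p = 0.0015, adjusted p = 0.05 after rounding), a list that camera did not call.

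The same predicted miRNA set the parents apart, while a difference in the most abundant one depended on the scaling. PC-169-5p was at 17332 ± 9124 CPM in C. hystrix and 11.8 ± 16.7 in C. sativus (+10.37, SE 1.62, adjusted p = 0.0013 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), so the level in the allotetraploid lay between the parents, nearer to C. hystrix on the log scale and nearer to C. sativus on the linear scale. Without the first C. sativus library the ratio between the parents was +15.24. miR166a (TCGGACCAGGCTTCATTCCCC; 1 of its loci on chromosome 3, 9416447–9416547, plus strand) was at 631428 ± 13128 against 117219 ± 47883 CPM (+2.43, SE 0.56, adjusted p = 0.044), a call that 4 of 24 alternatives shared (adjusted p from 0.0087 to 1). With the fragment-like families left out before scaling, PC-169-5p was the only entry called. With all families kept, the miR166 family sum differed by +1.87 with TMM, +2.20 with RLE, +0.85 with library totals and +0.33 with conserved families (adjusted p from 0.26 to 0.71). The conserved families include miR166 itself, and library totals count it too. Both scalings thus draw its difference toward 0 by construction, and their smaller values do not decide whether it is real. As miR166 held so large a share of all reads, its level weighs on that of every other entry. Higher in C. hystrix without a call were miR171u-p5 (at least 8.76-fold, adjusted p = 0.3), miR156i-p3 (+3.88), miR172g-p3 (309 ± 80.5 against 26.9 ± 23.8 CPM, +3.46) and PC-132-5p (42.5 reads against 2.5, counting interval of the ratio 6.13–201), the last 3 at adjusted p = 0.36. Higher in C. sativus were miR393b-p3 (−3.23, adjusted p = 0.36), a miR398a entry (−3.21, adjusted p = 0.46), miR397-p3 (−2.95), PC-198-3p (−2.44) and PC-20-3p (counting interval of the ratio 1.47–58), the last 3 at adjusted p = 0.95. The edgeR test called 2 of 208 entries, with 14 at unadjusted p < 0.05, of which 11 were higher in C. hystrix. DESeq2 called 3 and limma 1, and without the first C. sativus library edgeR called 45. With the preset correlation, the copper-protein list was called lower in C. hystrix, with 8 of 10 entries below 0 and a median of −1.22 (camera adjusted p = 0.0094). It was not called with the estimated correlation of 0.73 (camera adjusted p = 0.95), and 0 entries were called over all or over the list alone. The list call was lost without the second C. sativus library (median −0.65, camera adjusted p = 0.37) and without the second C. hystrix library (0.63), within a range of 1.4e-04 to 0.95, and the C. hystrix libraries themselves differed 7.47-fold in the median over this list. For the other lists the medians and camera adjusted p were +0.43 and 0.13 (juvenile/adult phase), +0.31 and 0.21 (conserved families), +0.39 and 0.22 (leaf growth) and +0.61 and 0.26 (shoot apex or primordia, for which fry passed at an unadjusted p of 0.002, adjusted p = 0.05 after rounding). The call of miR166a was the only one in these lists over all entries, while over the list alone there were 2 in leaf growth and 2 in shoot apex or primordia. Small RNA machinery had −0.32 and 0.36, auxin signalling +0.63 and 0.46, and nutrient +0.62 and 0.8. Phloem sap had a median of +0.44 but a mean of −0.23 (0.27), and GRAS/SCL a median of −0.21 but a mean of +0.40 (0.75).

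**Figure D3:**
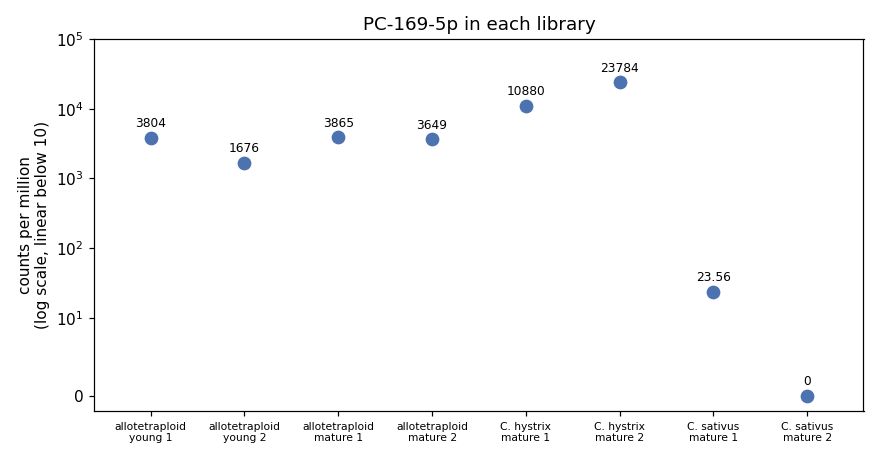
Counts per library size (CPM, log axis that is linear below 10) of PC-169-5p are drawn as 8 points, 1 per library, over the 4 groups. C. hystrix lies at 10880 and 23784, the mature allotetraploid at 3865 and 3649, its young leaves at 3804 and 1676, and C. sativus at 23.56 and 0.

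Non-additivity, the departure of the allotetraploid from the mean of its parents, was called for no miRNA. Among entries that met the naming rule, PC-169-5p (+2.98, SE 0.93, adjusted p = 0.52), PC-131-3p (+2.18) and miR156f (+2.14) lay above the log-scale mid-parent, and miR393c (−2.89, through 1 C. sativus library) below it. Without the first C. sativus library PC-131-3p was at +4.86 and miR156f at +5.36, as both had 0 CPM in the second. The others had 3 reads or fewer in a group, so only their levels are given. miR171u-p5 was at 125 CPM in the allotetraploid, 57.8 in C. hystrix and 0 in C. sativus (adjusted p = 0.52), and miR156d-p3 at 61.9, 2.95 and 20.2. On the lower side PC-20-3p was at 0, 4.72 and 27.8 CPM, miR169g at 6.72, 91.4 and 74.9, miR171c-p3 at 3.48, 33.1 and 16.9, and PC-58-3p at 1.74, 14.2 and 16.8. Scale matters for PC-169-5p: on the linear scale, its 3757 CPM lay below the mean of the parents, 8672 (−1.10, SE 0.68, adjusted p = 0.96 in limma). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 208 entries (smallest adjusted p 0.52), with 3 at unadjusted p < 0.05. The linear scale was tested with limma on log2 CPM with a pseudocount of 1, which called 0 with 7 at unadjusted p < 0.05. For it, the parental libraries of the same replicate number were averaged, though these numbers do not pair the samples. DESeq2 called 0 with 7, and limma on the deposited normalized reads 0 with 4. Without the first C. sativus library edgeR called 22, and without the second 2. Of all entries 117 lay above and 91 below the log-scale mid-parent, 105 and 103 on the linear scale, and 34 changed sign between the scales. By dominance class 206 entries were in the class no difference, that is, without a call in any pairwise test of mature leaves. PC-169-5p was classed as C. hystrix-like, as it had no call against C. hystrix, though at 3757 against 17332 CPM (−2.21). miR166a was in the class other, as a difference was called between the parents but not between the allotetraploid and either. A missing call does not show equal levels, since most simulated 16-fold changes were missed in these tests. No list was called: the medians and camera adjusted p were +0.71 and 0.089 (juvenile/adult phase), −0.17 and 0.3 (auxin signalling), −0.21 and 0.34 (small RNA machinery), −0.44 and 0.35 (copper protein), and +0.26 and 0.39 (leaf growth). They were +0.20 and 0.46 (conserved families), +0.19 and 0.56 (shoot apex or primordia), +0.49 and 0.74 (nutrient), +0.12 and 0.8 (GRAS/SCL), and +0.34 and 0.8 (phloem sap).

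Listed reads were mainly of 20 or 21 nt and mainly began with T, except in the second C. sativus library. The table lists miRNAs only, and miR166 and miR159 filled most libraries, so these shares do not test what kind of small RNA the leaves held. Sequences of 21 nt, the length made by DCL1, held 60.4 ± 7.26% of reads in young leaves, 56.2 ± 6.95% in the mature allotetraploid, 67.4 ± 5.02% in C. hystrix and 37.4 ± 0.391% in C. sativus. Those of 20 nt, the length of miR159a, held 33.4, 31.3, 21.5 and 28.2 ± 27% in the same order, with 47.3% and 9.07% in the C. sativus libraries. Sequences of 19 nt, among which is the most abundant miR5368 fragment, held 2.48, 7.17, 6.62 and 19.7 ± 13.5%, with 10.1% and 29.2% in the C. sativus libraries. A first T, the base preferred by AGO1, held 88.8 ± 0.0295% in young leaves, 82.4 ± 6.03% and 84.3 ± 0.739% in the mature allotetraploid and C. hystrix, and 60.9 ± 22.5% in C. sativus (76.9% and 45% in its libraries). For known versus newly predicted miRNAs, entries of PC name, taken here as predicted, made up 34.2 ± 7.48% of the entries detected per library but only 0.27% to 0.789% of reads. The 444 entries marked as new outnumber the 287 of PC name, so this split differs from the deposited marks. Of the 208 tested entries, 36 had a PC name and the others a family number. At unadjusted p < 0.05, 0 of the former and 27 of the latter differed between young and mature leaves (Fisher exact p = 0.00569), and in the other comparisons p lay between 0.0781 and 1. Of called entries between young and mature leaves, 0 and 4 were of these kinds (Fisher exact p = 1). Fisher's test takes entries as independent, whereas many are arms or variants of 1 family read in the same libraries. Its p of 0.00569 is therefore likely too small. Entries of PC name were mostly less abundant, and whether this accounts for the difference between the kinds was not tested.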

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

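Of the alternatives below, the fragment-like families left out, limma with a pseudocount of 1 and the reads summed over loci were chosen after seeing the data. With 1 library of a group left out, the lone sample is assumed to vary like the other groups. Why counts changed was not tested.

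For allotetraploid young leaf vs allotetraploid mature leaf (4 calls), DESeq2 gave 17 calls (5 higher, 12 lower), edgeR with RLE 7, every locus kept on its own 7, limma with quantile normalization 7, fragment-like families left out 8, limma with a pseudocount of 0.5 gave 1, and a fit of only the groups compared 43. Scaling to conserved families gave 0 (23 at unadjusted p < 0.05, smallest adjusted p 0.075 in edgeR). Left out singly, the libraries gave 0 to 32 calls: 0 without young 1 or young 2 (13 at unadjusted p < 0.05 in edgeR for each), 10 without C. hystrix 1, 7 without C. hystrix 2, 32 without C. sativus 1 and 24 without C. sativus 2. miR408-5p passed in 21 of 24 alternatives (adjusted p from 6.3e-08 to 0.33), miR408 in 20 (7.1e-06 to 0.33), miR397 in 19 (1.3e-07 to 0.33) and miR156i-p3 in 13 of 23 (1.7e-04 to 0.44). miR397 was also lost without mature allotetraploid 1 (0.11), and miR156i-p3 without mature allotetraploid 2 (0.25).

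For allotetraploid mature leaf vs C. sativus mature leaf (1 call), DESeq2 gave 4 calls, limma with quantile normalization 2 and scaling to conserved families 0 (27 at unadjusted p < 0.05 in edgeR). PC-169-5p then had +7.40 and adjusted p 0.068, the highest of 24 alternatives (lowest 2.9e-11). The range with 1 library left out was 1 to 55: 3 without C. hystrix 1, 2 without C. hystrix 2 and 55 without C. sativus 1. Against C. hystrix, edgeR, DESeq2 and limma gave 0 calls under all alternatives, with 0 to 11 entries at unadjusted p < 0.05.

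For C. hystrix mature leaf vs C. sativus mature leaf (2 calls), the count was 1 with RLE, library totals, conserved-family scaling, no filter, 10 CPM in every compared group, only the groups compared, entries summed by family, each of the 5 limma settings and the fragment-like families left out, and 5 with every locus kept. With 1 library left out it was 1 to 45: 45 without C. sativus 1 and 1 without any other. PC-169-5p passed in 24 of 24 alternatives (highest adjusted p 0.018), and miR166a in 4 of 24 (0.0087 to 1).

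For allotetraploid mature leaf vs mid-parent (0 calls), the range with 1 library left out was 0 to 22: 22 without C. sativus 1 and 2 without C. sativus 2. PC-169-5p then had +5.40 (adjusted p = 0.0011) and +2.68 (0.03), within 0.0011 to 1 over 25 alternatives.

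The miRNA list tests (4 calls) gave 2 with conserved-family scaling, 9 with 10 CPM in every compared group, 0 with an estimated correlation in camera (1 at unadjusted p < 0.05) and 2 others with fry. With 1 library left out they gave 2 to 10: 7 without mature allotetraploid 2, 10 without C. hystrix 1, 8 without C. sativus 1, and 2 without C. hystrix 2 or C. sativus 2. The copper list of young leaves passed in 16 of 18 alternatives (2.5e-09 to 0.95), as did the phase list (3.5e-05 to 0.95), the copper list between the parents in 13 (1.4e-04 to 0.95) and leaf growth in 9 (0.0086 to 0.95). List tests were not run with DESeq2.

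The parental dominance classes other than no difference (2 entries) numbered 5 with DESeq2 and with every locus kept. They numbered 1 with RLE, library totals, conserved-family scaling, no filter, 10 CPM in every compared group, only the groups compared, entries summed by family, limma at pseudocounts 1, 0.5 and 5 or without a filter, fragment-like families left out, and an adjusted p under 0.01. With 1 library left out they numbered 1 to 55, with 55 without C. sativus 1.

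With the replicate number as a block, though neither the labels nor the values pair the samples (correlations of same-numbered deviations 0.33 for young leaves and C. hystrix, −0.046 to 0.023 for the other groups), allotetraploid young leaf vs allotetraploid mature leaf gave 9 calls, the 4 among them. The same block gave 0 calls in edgeR against C. hystrix (1 at unadjusted p < 0.05), 1 against C. sativus, 3 between the parents and 0 against the mid-parent (7 at unadjusted p < 0.05), 5 in the miRNA list tests and 3 in the parental dominance classes.

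With reads summed over loci, the 21-nt share, allotetraploid young, was 82%, and the 21-nt share, allotetraploid mature, 77%. The 21-nt share, C. hystrix mature, was then 84.6%, and the 21-nt share, C. sativus mature, 52.8%. Of 1173 other values, 1086 kept sign and call, 41 gained a call, 43 lost it and 3 moved otherwise.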

Other observations

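miR393, which curbs the TIR1/AFB auxin receptors and was named above by single members, had its highest family value in 1 C. sativus library. The family stood at 659.7 and 3264 CPM in C. sativus, 336.9 and 566.5 in C. hystrix, and 201.1 and 428.2 in the mature allotetraploid (−2.64, SE 0.99, against C. sativus, adjusted p = 0.27 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over families and entries without a family, and 0.031 to 0.4 over the scalings). Its members differed there, as miR393a-3p was at 40.49 CPM in that library and at 764.1 in the other. The miR390 family was at 1409 and 1067 CPM in young and 224.1 and 153.5 in mature leaves of the allotetraploid (+2.71, SE 0.97, adjusted p = 0.1). miR827, a phosphate-status miRNA, was at 28.7 CPM in young and 206 in mature leaves (−2.83, adjusted p = 0.21). These families were picked after their values were seen, and none passed with TMM.

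Tests chosen only after the result was seen were the one for a wrong label and the one for a condition tied to the replicate number. First, the second C. sativus library stood apart from the first. Fragments in place of miRNA reads are argued against as the whole cause, since without the fragment-like families the correlation stayed at 0.568 (163 entries) against 0.824 or more in the other groups, a difference of −0.255 with a bootstrap SE of 0.055. Low depth is argued against likewise, as it was 0.377 over the 58 most abundant entries, against 0.75 or more (difference −0.374, SE 0.12). A C. hystrix or allotetraploid library under a wrong label is argued against by 1 entry, PC-169-5p, which had 1676 to 23784 CPM in their 6 libraries and 0 CPM here, where 3 reads would be 15.2. RNA breakdown and a difference between plants stay open as untested.

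Second, copper-protein miRNAs were higher in replicate 1 than in replicate 2 of both mature C. hystrix and the mature allotetraploid, in 10 of 10 entries of each (9 of 10 in the latter with RLE). Scaling or depth is argued against: the lowest median ratio over 4 scalings and both groups was 4.04. A condition that acts alike on all libraries of one number was asked of the other groups. The median log2 ratio was 2.01 or more in the groups of the pattern. In C. sativus it was −0.1 with TMM and −0.82, −0.78 and −1.77 with RLE, totals and conserved families. That ratio rests on the second C. sativus library, which stood apart, and its SE of 0.44 takes entries that move together as independent. In young leaves the median was 0.64 at most, with 8 of 10 entries higher in replicate 1, the direction of the pattern. These values leave such a condition undecided. A condition shared by only these groups, or met differently by C. sativus and by young leaves, and the copper or light status of single plants, stay open as untested.

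Last, PC-169-5p was near 0 in C. sativus and high in the other groups. A C. sativus variant of the sequence counted under another entry would leave a similar sequence in the table, and 0 entries lay within 3 differences. Since the table need not list such a variant, it cannot be told apart from a true absence. A difference between the parents at this locus, carried on by the allotetraploid, may be behind it and was not tested.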
